A study of Homo sapiens with 12 samples.

How the data were processed

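Gene expression was measured on 12 Illumina BeadChip arrays of U87MG cells, an established human glioblastoma line, either with SLFN5 (WT) or with SLFN5 knocked out (KO), and either untreated or given human interferon beta (IFNβ) at 5000 IU/ml. The treatment lasted 6 hours. Per the labels, biotin-labelled cRNA was made from 150 ng of total RNA.

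The deposited linear table holds 1 scanner intensity per probe and array for 47323 probes, on a linear scale, and the authors' steps before it are not given in the sources used here. Array medians of that intensity lie between 92.6 and 106.3. The second deposited table holds the authors' processed log2 values of the same arrays, with values from 4.12 to 14.6 and column medians of 4.54, equal across arrays to 2 decimals. Its scale and common distribution were read from the values, and its background correction and normalization are not given in the sources used here.

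The labels contradict each other. Each sample has a title, which its characteristics repeat, and a short code in its description, and for 8 of 12 arrays the title names another group than the code at the head of the linear table. The accession-named columns of the log2 table were matched to the coded columns of the linear table by rank correlation over all probes. Each matched exactly 1 array, with a lowest matched rank correlation of 0.9999 and a highest correlation with another array of 0.84. For 10 arrays the description code and the column code were the same. For the remaining 2, both KO replicate 3, the tables exchange the untreated and the IFNβ code. The rule fixed before the data were examined groups a coded column by its code, and taken literally it includes all 12 arrays. The main comparisons leave out the 2 arrays with contradicting codes, so that WT has 3 arrays and KO has 2 arrays per treatment. That departure was decided after the array correlations had been seen, which also show which arrays resemble each other, and before any gene was tested. Fits with all 12 arrays, coded either way, are given beside the results they change. The groups rest on the codes, against the titles of most arrays.

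The linear table has no detection p-values, so the planned background fit from them was replaced by the fallback named in the plan: normexp background correction with an offset of 50, quantile normalization and log2, over all 12 arrays (limma 3.58.1 in R 4.3.3). The offset shrinks fold changes of dim probes. The planned detection filter was replaced by a stand-in: a normal curve was fitted to the dim side of each array's most frequent log2 signal, and a probe counted as above background at p under 0.05 of that curve. Between 17801 and 19167 probes per array were above background, 37.6% to 40.5% of all. Probes above background on at least 3 of the 12 arrays were kept, 20945 in all. Of the 47323 probes, 30113 have 1 gene symbol in the platform annotation, 8 have several and 17202 are not listed there and stay unnamed. Names were checked through Entrez identifiers against the gene table of assembly GRCh38.p14, used for names and gene order only, and 0 symbols changed. The probe with the highest mean stood for each gene, which left 11592 genes; 3061 of them had more than 1 probe passing the filter. For named genes with other probes, the sign of another probe differed for CERK and RFC3 in the interferon change in KO, for CASP4 and HOPX between untreated KO and WT, and for PCDH10 between KO and WT with IFNβ. Among other probes of named genes, 11 of 27 for IFNβ in WT, 12 of 27 in KO, and 7 of 13 between KO and WT, untreated and with IFNβ alike, had the same sign but under 50% of the representative probe's change, so sizes depend on the probe.

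Group means were fitted with lmFit over all 4 groups, contrasts were tested with eBayes, two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested; a gene was called at an adjusted p under 0.05. Errors of changes are SE from that fit, and group values are mean ± SD. Where a probe was below background on every array of the dimmer group, the change is given as a bound: the bright group's mean against, per array, the higher of the dim probe's value and the lowest value among probes above background. A difference in response with such a group among its 4 groups is given no size. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, and again with an estimated correlation; of 32 lists, 27 had at least 5 measured members. Named genes are SLFN5, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap (adjusted p alone for the difference in response), up to 4 called members of each described list with the largest change, or up to 2 given as values where none was called, and for the difference in response STAT2, IRF9, IFIT1, ISG15, CXCL10 and MX1. STAT2 was not analysed here, CXCL10 was above background on 0 arrays, and a further gene of that rule is not reported here.

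Replicate numbers were checked for pairing. In the 10 arrays, deviations from group means correlated across genes between 0.29 and 0.57 in the 13 pairs of same-numbered arrays of different groups, against -0.57 to 0.26 in the 24 pairs with different numbers. The numbers, taken from the codes, were therefore read as pairing the samples. The main fit, as planned, has no block, so its SE and adjusted p ignore that pairing. Fits with the number as a block are given where they change a result. No source says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The small number of arrays limits the precision. No pair of arrays shared over 1% of its values. No file gives slides, so slide was not modelled.

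The fit was tested on simulated arrays with 200 changed genes per comparison among 11592. Simulated noise was independent between genes and arrays, and changes were added to normalized values. The correlation of same-numbered arrays and the shrinkage of dim probes are thus left out of the shares below. For the interferon change in WT it recovered 95.7% of changes of 1 on the log2 scale, for that in KO 81.3%, and for the difference in response 63.9%. For changes of 0.5 those shares were 56.9%, 22.6% and 4.92%. Alternatives were other scaling, no background correction, an offset of 16, the deposited log2 values, other filters, every probe on its own, only the compared groups, trended and robust variance, array weights, the block, each array left out, and the other codings of the arrays.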

Results

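The series holds 4 groups of U87MG glioblastoma cells, WT or SLFN5 knockout, untreated or treated with IFNβ, a type I interferon. After leaving out the 2 KO arrays whose codes contradict each other between the deposited tables, there were 3 WT and 2 KO arrays per treatment. Groups follow the codes; with the deposited log2 values of all 12 arrays grouped by sample title, 0 genes were called in each of the comparisons between groups (limma; 470, 472, 621 and 443 at unadjusted p under 0.05 for IFNβ in WT, IFNβ in KO, KO against WT untreated and KO against WT with IFNβ). By the codes each title group mixes both lines and both treatments, so that count of 0 may come from the grouping alone. The title of the series concerns the role of SLFN5, a member of the Schlafen family of interferon-induced genes, in type I interferon signalling.

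SLFN5, the targeted gene, rose with IFNβ in WT cells by 0.70 ± 0.12 on the log2 scale (SE, adjusted p = 0.0035), from 6.25 ± 0.18 to 6.94 ± 0.06 (SD, n = 3 each). In KO cells its change was 0.07 ± 0.15 (adjusted p = 0.923), with 6.23 ± 0.12 untreated and 6.29 ± 0.26 with IFNβ (SD, n = 2 each). The difference between the 2 changes was -0.63 ± 0.20 and did not pass (adjusted p = 1, and 0.453 with the replicate number as a block). With IFNβ it was lower in KO than in WT, with a difference of -0.65 ± 0.14 (adjusted p = 0.0255). Untreated, the difference was -0.02 ± 0.14 (adjusted p = 0.978). The single SLFN5 probe was near background, above it on 2 of 3 untreated WT arrays and on 1 of 2 arrays in each KO group, so a difference in the untreated level was not detectable at this signal. The call with IFNβ was lost with 75th percentile scaling (adjusted p = 0.0701) and without any single one of the WT IFNβ arrays or KO IFNβ replicate 1 (0.0634 to 0.243). No source used here places the probe against the edited part of the gene, so its signal may not report the edit.

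**Figure D1:**
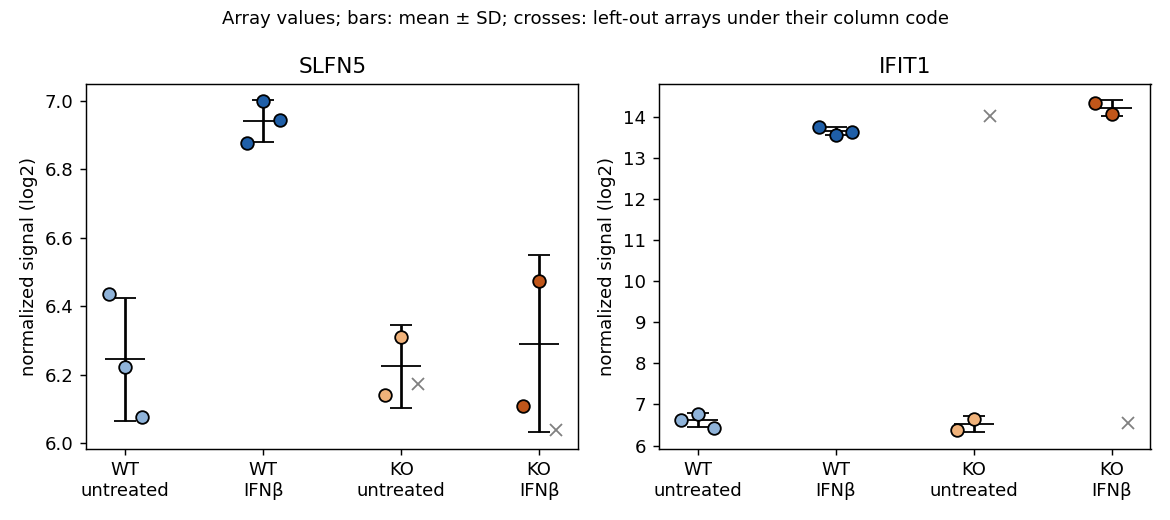
Normalized log2 signal of SLFN5 and IFIT1 on each array, by group, with mean and SD bars over the arrays used. Crosses are the 2 left-out KO arrays under their column codes; IFIT1 is at 14.0 in the one headed untreated and at 6.56 in the one headed IFNβ.

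IFNβ in WT cells raised the classical antiviral genes most. IFIT1, which binds foreign RNA, rose by 7.04 ± 0.12 on the log2 scale, IFIT2 by 7.02 ± 0.13, IFIT3 by 6.36 ± 0.16 and OAS2, an oligoadenylate synthetase, on its brightest probe by 6.25 ± 0.10 (largest adjusted p = 9.74e-12). Other probes changed less, by 1.24 to 2.18 for OAS2, 3.28 for IFIT1 and 2.60 and 6.17 for IFIT3. IFI27 was at least 34.0-fold higher, its untreated signal being below background. ISG15, a ubiquitin-like modifier, ISG20, OASL, MX2, HELZ2, OAS1 and IFIH1 rose by 4.47 to 4.84 (1.49 to 4.67 on other OAS1 probes). The falls were smaller: CERK, ceramide kinase, fell by 1.94 ± 0.13 on its brightest probe (-0.14 on the other), HNRNPA0 fell by 1.81 ± 0.15, the long noncoding RNA DANCR fell by 1.73 ± 0.14 and UBL3 fell by 1.43 ± 0.11.

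Among the fixed lists, 51 of 54 measured antiviral effectors rose in WT cells (53 adjusted over the list alone; median 2.81, camera adjusted p = 4.75e-154). Of 17 nucleic acid sensing genes 10 rose, among them IFIH1, RIGI at 3.51 ± 0.16, AIM2 and MYD88 (11 adjusted over the list alone; camera adjusted p = 2.21e-23). Of 19 genes of MHC class I antigen presentation 11 rose, led by the peptide transporter TAP1 at 2.94 ± 0.17 (13 adjusted over the list alone). IRF7, IRF9, BATF2 and IRF1 rose among 11 IRF transcription factors (4 adjusted over the list alone), and TNFSF13B, TNFSF10, IL15 and IL7 were among 6 of 9 cytokines that rose (7 adjusted over the list alone). Of 16 cell death genes 6 rose, led by MLKL and CASP1 (7 up and 1 down adjusted over the list alone), and of 18 immediate early genes 4 rose, led by KLF6 (6 adjusted over the list alone). Of 22 receptor and JAK-STAT genes 6 rose and 1 fell (7 and 1 adjusted over the list alone). All 4 measured guanylate-binding proteins rose, GBP2 by 2.07 ± 0.17 among them. The hypoxia list was also called (adjusted p = 0.0145) with 1 of 19 members up, the hexokinase HK2 (2 adjusted over the list alone), but not with an estimated correlation (adjusted p = 0.71), with 75th percentile scaling (0.0826), without WT IFNβ replicate 1 (0.199) or without WT untreated replicate 2 (0.202); the other 8 called lists held with an estimated correlation. With the replicate block 5 hypoxia genes and 7 immediate early genes rose. No member of the 33 cell cycle or 29 DNA replication genes was called without the block. With it TOP2A, E2F2 and CENPA of the first list and RFC3, PRIM1 and MCM10 of the second, named after their values were seen, were lower with IFNβ at -0.49 to -0.34 (largest adjusted p = 0.0423). The cell cycle list was called lower with the block (camera adjusted p = 0.00924, against 0.158 without it), but not with the block and an estimated correlation (adjusted p = 0.373).

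In WT cells 384 genes rose and 139 fell, of 11592 tested with limma; 147 rose and 10 fell at least 2-fold. With the replicate number as a block the counts were 609 and 491. With all 12 arrays grouped by column code, which includes the 2 contested arrays, 0 genes were called (limma, with 1194 at unadjusted p under 0.05). That coding places a KO array with IFIT1 at 14.0 under untreated and one at 6.56 under IFNβ. Both contested arrays are KO, so the WT changes are the same under that coding. The WT calls were lost through the estimate of the spread, which all 4 groups share in the fit. Lost calls and turned signs of comparisons with KO arrays, below, may come from exchanged codes alone.

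In KO cells IFNβ also raised antiviral genes most. IFIT1 rose by 7.69 ± 0.15, IFIT2 by 7.33 ± 0.15, IFIT3 by 6.59 ± 0.20 and ISG15 by 5.35 ± 0.11 on the log2 scale (largest adjusted p = 8.94e-11). OAS2 was at least 80.5-fold higher on its brightest probe, IFI27 at least 31.0-fold and MX2 at least 29.0-fold higher. Other probes changed by 0.94 to 2.06 for OAS2, 4.15 for IFIT1 and 2.81 and 6.51 for IFIT3. GBP1, a guanylate-binding protein, rose by 4.67 ± 0.20 and the cytokine TNFSF13B by 4.63 ± 0.17. UBL3 fell by 1.86 ± 0.13, HNRNPA0 fell by 1.77 ± 0.18, CERK fell by 1.65 ± 0.15 (0.16 on its other probe) and the G protein regulator RGS2 fell by 1.21 ± 0.23.

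Of 54 antiviral effectors 50 rose in KO cells (54 adjusted over the list alone; median 2.93), and of 17 nucleic acid sensing genes 10 rose, among them IFI16, which rose by 2.50 ± 0.16 (11 adjusted over the list alone). In MHC class I presentation 9 of 19 rose, and in the cytokine list 5 of 9 (12 and 6 adjusted over the list alone). All 8 called lists held with an estimated correlation, but with the block added the immediate early list did not (camera adjusted p = 0.0999). CCNE1, a cyclin, fell by 0.58 ± 0.13, the only called member of 33 cell cycle genes (1 adjusted over the list alone), and RFC3, on its brightest probe, fell by 0.78 ± 0.16, the only one of 29 DNA replication genes (2 adjusted over the list alone). With the block 4 and 3 members of these lists fell. The call of RGS2 was lost without KO IFNβ replicate 2 (adjusted p = 0.0646), and those of CCNE1 and RFC3 without KO IFNβ replicate 1 (0.17 and 0.0796) or KO untreated replicate 2 (0.0743 and 0.101); CCNE1 was also lost without KO untreated replicate 1 (0.0945). With the KO groups fitted alone, CCNE1 and RFC3 were not called (0.146 and 0.0965).

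In KO cells 399 genes rose and 122 fell, and 179 rose and 14 fell at least 2-fold (limma). With the block the counts were 608 and 521; fitting the 2 KO groups alone gave 253 and 33. Grouping all 12 arrays by description code gave 556 and 419, and by column code 0 (limma; 233 at unadjusted p under 0.05).

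Both lines shared 318 rises and 56 falls, against 13.2 and 1.46 for independent lists, and 0 genes were called in opposite directions. With the replicate block 466 rises and 232 falls were shared, against 31.9 and 22.1. Of 670 genes called in either line, 665 had the same sign in both. Across genes, which are not independent replicates, the changes correlated with r = 0.893 and rho = 0.545. Of 149 genes called in WT alone and 147 called in KO alone, 0 differed between the lines in limma's test of the difference itself, in which 306 of all genes had an unadjusted p under 0.05. On simulated arrays that test recovered 4.92% of differences of 0.5 and 63.9% of differences of 1, so the 0 does not show equal responses.

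**Figure D2:**
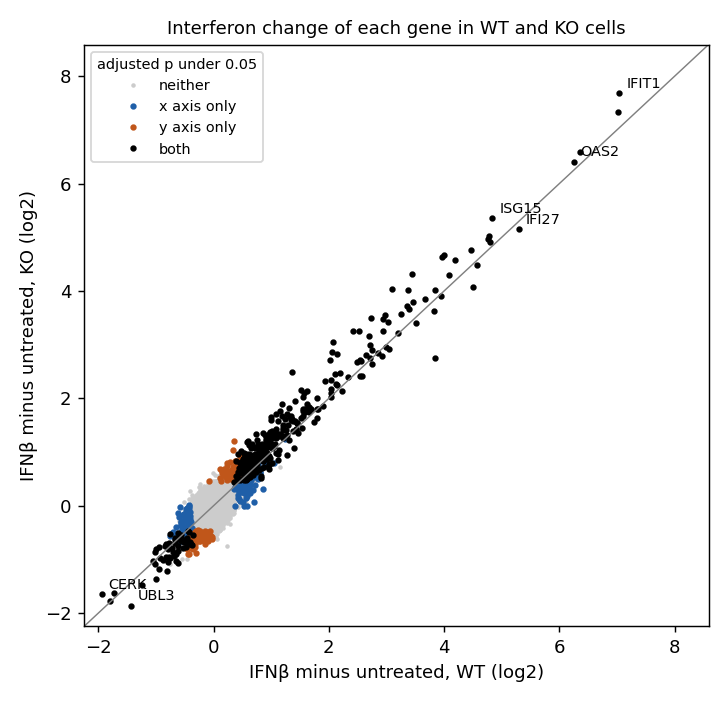
Change of each of 11592 genes with IFNβ in WT (x axis) and in KO (y axis), log2 scale, coloured by adjusted p under 0.05; the line marks equal change. Most called genes lie near the line, and IFIT1 is at 7.04 and 7.69.

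Before interferon, KO cells had less BEX1 than WT cells, a difference of -3.50 ± 0.29 on the log2 scale on its brightest probe and -0.36 on the other, less AQP9, a water and glycerol channel, at -2.88 ± 0.20, and less CTSK, the collagen-degrading cathepsin K, at -2.48 ± 0.20 (largest adjusted p = 1.7e-05). SBSN, VGF, CHI3L1, NT5E and the receptor IL13RA2 were lower by differences of -2.44 to -2.00. On their brightest probes SLC25A4 was at least 4.16-fold and TFAP2C at least 2.71-fold lower, and their other probes differed by -0.96 and -1.19. BGLAP, osteocalcin, was higher by 2.31 ± 0.14, C5orf46 by 1.91 ± 0.21, the plasminogen activator PLAT by 1.82 ± 0.37 and HOPX, on its brightest probe, by 1.48 ± 0.15 (-0.09 on the other), and PCDH10 was at least 2.16-fold higher on its brightest probe (0.12 and 0.30 on the others).

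Of 17 nucleic acid sensing genes 3 were lower in untreated KO cells, IFI16 at -0.94 ± 0.15, AIM2 at -0.86 ± 0.13 on its brightest probe and -0.13 on the other, and MYD88 at -0.63 ± 0.13 (3 adjusted over the list alone). Among 16 cell death genes MLKL was lower, at -0.76 ± 0.11, and so was CASP4 on its brightest probe, at -0.58 ± 0.13 (2 up and 3 down adjusted over the list alone, and as many with the block). The other CASP4 probes differed by -0.11 and 0.04. Of 17 glycolysis genes ALDOC, at -1.51 ± 0.26, and LDHB were lower (2 adjusted over the list alone). Grouped by column code over all 12 arrays, AIM2, MYD88 and MLKL had the opposite sign (0.26, 0.07 and 0.33, none called). The DNA replication list (median -0.08) and the oxidative phosphorylation list (median -0.12) were called lower, both with camera's adjusted p = 0.0321 and 0 members called (2 and 1 adjusted over the list alone, 3 and 1 with the block). Neither call held with an estimated correlation (adjusted p = 0.957 and 0.40) or with the replicate block (both 0.0707). The first was also lost without KO untreated replicate 1 or WT untreated replicate 3 (0.61 and 0.183), the second without WT untreated replicate 2 or 3 or KO untreated replicate 2 (0.0771, 0.137 and 0.0872), and both with 75th percentile scaling (0.0816 and 0.0514), an offset of 16 (0.0736 and 0.0994) and the deposited values grouped by code (0.0999 and 0.139). Of the markers of other cell types, none passed the test over all genes. The macrophage marker CSF1R, at -0.48 ± 0.14, and the neuron marker GAD1, at -0.43 ± 0.12, were lower adjusted over the list alone, and with the block over all genes (adjusted p = 0.0195 and 0.0353). CD68 and TUBB3, the brightest, differed by 0.05 and -0.17.

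In all, 119 genes were higher and 162 lower in untreated KO cells (limma), and 408 and 394 with the block. The total of 281 was 125 without KO untreated replicate 1, 175 without KO untreated replicate 2, 177 without WT untreated replicate 1 and 161 without WT untreated replicate 3. Without KO untreated replicate 1, PLAT, MYD88, CASP4, ALDOC and LDHB were not called (adjusted p = 0.206, 0.168, 0.169, 0.0683 and 0.115), and the PLAT difference was 1.10. PLAT also lost its call without WT untreated replicate 1 or 3, without background correction (0.0575) and with trended, robust variance (0.16), and MYD88 and CASP4 without either KO untreated array and without WT untreated replicates 1 and 2. CASP4 was also lost without WT untreated replicate 3 or WT IFNβ replicate 1 and with an offset of 16 (0.0624), MYD88 without background correction (0.0553), and LDHB with 75th percentile scaling (0.0546). Over all 12 arrays the total was 537 by description code.

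With IFNβ the largest differences included BEX1 at -3.63 ± 0.29 (-0.29 on its other probe), AQP9 at -2.84 ± 0.20, CTSK at -2.55 ± 0.20, BGLAP at 2.40 ± 0.14 and C5orf46 at 1.96 ± 0.21. Between the 2 treatments, which share no array, 68 higher and 106 lower genes were common (230 and 246 with the block), against 1.61 and 2.35 for independent lists (16.9 and 15.02 with the block). Those values leave out the replicate effects that same-numbered arrays of both treatments share. In 100 simulations of arrays with no change, same-numbered arrays were correlated at 0.569. Across genes the differences then correlated with a mean r of 0.208, against 0.735 in the data. Common genes numbered 0 in either direction (limma). With no change simulated hardly any gene can be called, so that 0 cannot show how far shared replicate effects raise the overlap. DKK3, a Wnt antagonist, was lower, at -1.63 ± 0.27, and the homeobox gene MSX1 higher by 1.26 ± 0.17.

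Among 54 antiviral effectors 6 were higher and 1 lower in IFNβ-treated KO cells (10 and 1 adjusted over the list alone, and as many with the block). MX1 was higher by 1.04 ± 0.20, DDX60 by 1.03 ± 0.18 and HERC6 by 0.85 ± 0.15, while RSAD2, viperin, was lower at -1.14 ± 0.15. IL15, TNFSF10 and TNFSF13B were higher among 9 cytokines, by 0.82 to 0.90 (3 up and 1 down adjusted over the list alone). By column code, over all 12 arrays, MX1, HERC6, TNFSF10 and TNFSF13B had the opposite sign (-0.06, -0.60, -0.39 and -0.82, none called). Both lists were called higher (adjusted p = 0.0018 and 0.0071) and the DNA replication list lower (0.0018), with 1 of 29 members called, the helicase subunit MCM2 at -0.51 ± 0.11 (3 adjusted over the list alone, 4 with the block). None of these calls held with an estimated correlation (adjusted p = 0.618, 0.618 and 0.927), and the cytokine list was not called with the replicate block (adjusted p = 0.052). By column code the antiviral list was called lower (adjusted p = 0.000842), and the cytokine list had the opposite direction (0.539). Without KO IFNβ replicate 1 the antiviral, cytokine and DNA replication lists were not called (0.128, 0.0776 and 0.636). Of the markers of other cell types, CSF1R, at -0.53 ± 0.14, and GAD1, at -0.36 ± 0.12, were lower adjusted over the list alone, and CSF1R with the block over all genes (adjusted p = 0.00824).

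With IFNβ 157 genes were higher and 168 lower in KO cells (limma), and 480 and 442 with the block. The total of 325 was 164 with 75th percentile scaling, 103 without KO IFNβ replicate 1, 201 without KO IFNβ replicate 2, 153 without WT IFNβ replicate 1 and 171 without WT IFNβ replicate 3. Without KO IFNβ replicate 1, DDX60, HERC6, TNFSF10, TNFSF13B and MCM2 were not called (adjusted p = 0.0936, 0.0956, 0.0554, 0.162 and 0.117), and the DDX60 difference was 0.64. Without KO IFNβ replicate 2, MX1, DKK3 and MCM2 were not (0.115, 0.0603 and 0.141). TNFSF13B also lost its call without WT IFNβ replicate 3 and with an offset of 16 (0.0508), and MCM2 without any single one of the WT IFNβ arrays, with an offset of 16 (0.0661) and with 75th percentile scaling (0.143). Over all 12 arrays the total was 611 by description code.

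**Figure D3:**
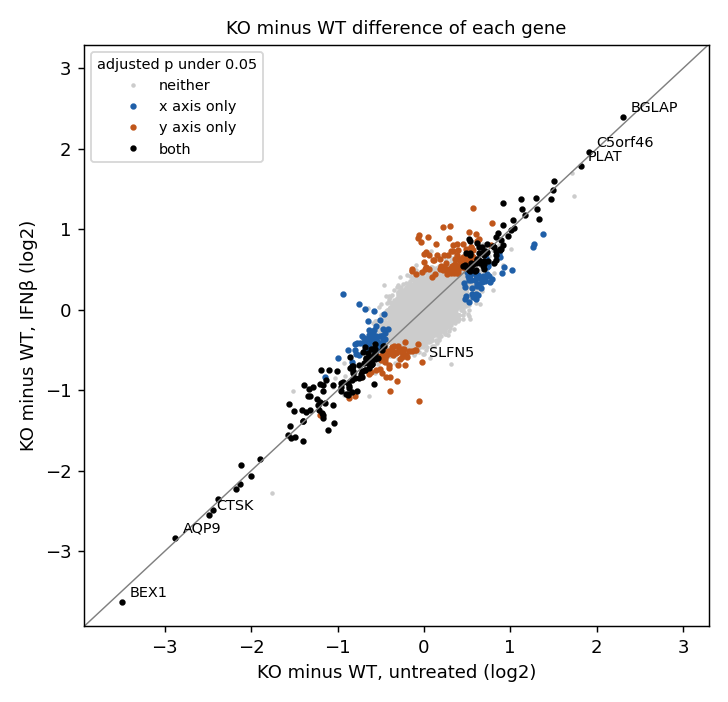
KO minus WT difference of each gene, untreated (x axis) and with IFNβ (y axis), log2 scale, coloured by adjusted p under 0.05; the line marks equal difference. BEX1 is at -3.50 and -3.63, and BGLAP at 2.31 and 2.40.

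The test of the series' question is the difference between the 2 interferon responses. The KO minus WT response was 0.65 ± 0.20 on the log2 scale for IFIT1, 0.52 ± 0.15 for ISG15 and -0.12 ± 0.18 for IRF9; none of these passed (each adjusted p = 1). MX1 was above background on 0 of 3 untreated WT arrays, so its difference, which did not pass either (adjusted p = 1), is given no size. With limma 0 genes were called, and 306 had an unadjusted p under 0.05. With the replicate block 4 were called higher and 2 lower. The higher ones were IFI16, GBP2 and MLKL, with differences of 1.14, 0.98 and 0.83, and TNFSF10, and the lower ones EXOSC8, at -0.99, and RSAD2 (largest limma adjusted p = 0.0335). For IFI16 and MLKL most of the difference lies in the untreated level, which was lower in KO at -0.94 and -0.76. GBP2 and TNFSF10 were higher in KO with IFNβ, by 0.93 and 0.89. TNFSF10 and RSAD2 were below background on every untreated array used, so their differences are given no size, and EXOSC8 was named after its values were seen. With all 12 arrays by description code and the block, 7 were called higher and 1 lower, RSAD2, while EXOSC8, at -0.71, was not called (adjusted p = 0.337).

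As groups, antiviral effectors responded more in KO (median 0.19, 41 of 54 positive, camera adjusted p = 6.34e-08), as did nucleic acid sensing genes (median 0.13, adjusted p = 0.0015) and interferon-associated cytokines (median 0.16, adjusted p = 0.0014). With an estimated correlation none of the 3 was called (adjusted p = 0.15, 0.15 and 0.412). With members below background on every array of a group set to the floor, the medians were 0.17, 0.13 and 0.16. Without those members, 33 of 42 antiviral genes, 8 of 13 sensing genes and 3 of 5 cytokines were positive, so the last 2 lists rest on few members. Adjusted over the list alone, 2 antiviral genes were higher and 1 lower, 2 sensing genes were higher and 3 cytokines were higher. Without KO IFNβ replicate 1 the sensing and cytokine lists were not called (adjusted p = 0.0858 and 0.0719), nor without KO untreated replicate 2 (0.0631 and 0.15). With all 12 arrays by column code all 3 had the opposite direction (camera adjusted p = 2.86e-22, 0.000793 and 0.00181). Under that coding IFIT1 is at 14.0 in a KO array counted as untreated and at 6.56 in one counted as IFNβ-treated. The reversal may therefore come from exchanged codes alone.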

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

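The tests of the slope, the titles and the untreated level were chosen after the result was seen, as were the use of the estimated correlation and the replicate block to weigh explanations, though both fits were fixed before the data were examined, and the rule by which the copy number test is read.

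An interferon signal appeared in an array that the comparisons leave out: in the KO replicate 3 array headed untreated, the median log2 value of the antiviral list was 10.53, against at most 6.84 in the untreated arrays used. The change from the array headed IFNβ to the one headed untreated followed the interferon change of KO replicates 1 and 2 with a slope of 0.979 across 521 genes, 517 of them in the same direction. This is consistent with codes exchanged in the linear table and argues against an exchange in the accession-named table, which needs a negative slope. In the treatment they name, the titles are argued against as well. Over the 10 arrays used the antiviral median spanned up to 3.75 within a title group and at most 0.27 within a code group. Over all 12 arrays the widest span was 3.75 by title, 3.81 by column code and 0.29 by description code. That median hardly differed between the lines, at 6.715 and 6.723 in untreated WT and KO replicate 1 and 6.836 and 6.83 in replicate 2. It therefore cannot test which arrays are WT or KO, and the genotypes rest on the codes. Values do not settle a label, so both KO replicate 3 arrays stayed out of the comparisons, and no biological explanation was tested.

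With a preset correlation the interferon response was called different between KO and WT for antiviral effectors (camera adjusted p = 6.34e-08), nucleic acid sensing genes (0.0015) and interferon-associated cytokines (0.00139), but none of these calls held with an estimated correlation (adjusted p = 0.15, 0.15 and 0.412), and the sensing and cytokine lists were not called without KO IFNβ replicate 1 (0.0858 and 0.0719) or KO untreated replicate 2 (0.0631 and 0.15). For the antiviral list, the tables argue against scaling of the arrays, since the median of 0.19 was 0.254 with 75th percentile scaling, and against 1 stronger culture, since the medians of replicates 1 and 2 were 0.196 and 0.197. List genes that vary together between cultures are a candidate explanation, since with an estimated correlation of 0.06 the adjusted p was 0.15. A lower untreated level in KO stays open: the untreated difference was -0.069, and its size stayed under the bound of 0.0925 set for it by less than the SD of 0.028 between replicates 1 and 2, while it was -0.019 with the 12 of 54 members that were below background on every array of an untreated group set to the floor and -0.08 without them. Loss of SLFN5 stays open and untested against other differences between the lines.

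Before interferon, 281 genes differed between KO and WT, and 125 to 322 with 1 array left out. With the replicate number as a block 802 genes were called, all 281 among them, so these calls did not depend on leaving the number out of the fit. That count cannot decide on a replicate batch. Each KO replicate number was also present in WT, so a batch tied to the number largely cancels from the difference. The block raised the count in every comparison, and it cannot remove a batch that differs between the lines. Copy number differences between the lines are a candidate explanation for part of the difference: across genes, the KO minus WT change correlated with that of the gene 10 places further along the chromosome at 0.0896, above the highest of 100 shuffled orders at 0.0244. For the interferon change in WT that correlation was 0.0051, below the highest shuffled value of 0.0242. Loss of SLFN5 and other differences between the lines were not separated, since the labels name no second KO line.

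For the interferon change in WT, the 6 arrays allow 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 523 genes and the highest of the others 0.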

How the results depend on the processing

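The placements of all 12 arrays by column code or description code, the deposited log2 values grouped by code, and the estimated correlation with the replicate number as a block were chosen after seeing the data. The cause of a change was not tested except where fewer arrays or genes account for it. The 247 named results are 222 gene calls and 25 list calls, a gene or list called in several comparisons counting each time. Strict filtering kept 246 calls, array weights 241, no filter 238, trended and robust variance 234 and no background correction 231. An offset of 16 kept 230, the deposited values grouped by code 225 and 75th percentile scaling 218. In each, every other result lost its call in the same direction. Every probe on its own kept 218 of 222 gene calls, and fitting only the compared groups kept 199. Dim signal limits SLFN5, which was above background on 1 of 2 arrays in each KO group. No file gives the slide, so the slide block was not run. Lists were not tested probe by probe or in fits of the compared groups alone, and the latter have no test of the difference in response.

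With 75th percentile scaling, 164 genes differed between KO and WT with IFNβ, the SLFN5 difference there was -0.59 (adjusted p = 0.0701) and 0 lists were called between untreated KO and WT. An offset of 16 and the deposited values grouped by code also called 0 lists there. With an estimated correlation 0 lists were called between KO and WT untreated, with IFNβ, or in the difference in response. Fitting the KO groups alone called 286 genes for IFNβ, with fewer arrays.

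With the replicate number as a block, the counts were 1100 for IFNβ in WT, 1129 for IFNβ in KO, 802 and 922 between KO and WT untreated and with IFNβ, 6 for the difference in response and 698 shared by the responses. The block ended the calls of both lists between untreated KO and WT, leaving 0, and of the cytokine list with IFNβ, and no other named call, and it added the cell cycle list, lower with IFNβ in WT (adjusted p = 0.00924). With the block and an estimated correlation 0 lists were called between KO and WT untreated, with IFNβ, or in the difference in response, and the immediate early list was not called for IFNβ in KO (0.0999). With all 12 arrays by description code and the block, the counts were 1113, 1691, 1240, 1443, 8 and 829, and 1 list was called between untreated KO and WT. Without the block they were 975 for IFNβ in KO, and 537 and 611 between KO and WT untreated and with IFNβ.

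Leaving out each array in turn gave 372 to 540 genes for IFNβ in WT, 364 to 520 in KO, 125 to 322 between KO and WT untreated, 103 to 332 with IFNβ, 0 to 1 for the difference in response and 306 to 345 shared. Where 1 array remained, it was assumed to vary like the other groups. SLFN5 ranged from 0.61 to 0.79 for IFNβ in WT, from -0.12 to 0.25 in KO, from -0.11 to 0.075 between KO and WT untreated, from -0.83 to -0.47 with IFNβ and from -0.81 to -0.45 for the difference in response. Its uncalled values changed sign, in KO to -0.02 without KO untreated replicate 1 and -0.12 without KO IFNβ replicate 2, and between untreated lines to 0.07 without KO untreated replicate 1 and 0.075 without WT untreated replicate 1. Called lists ranged from 8 to 14 and 8 to 18 for IFNβ in WT and KO, 0 to 8 and 2 to 6 between KO and WT untreated and with IFNβ, and 3 to 10 for the difference in response.

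With all 12 arrays by column code, 0 genes were called for IFNβ in WT or KO (limma, with 1194 and 233 at unadjusted p under 0.05) and 0 were shared. This coding counts as untreated the KO replicate 3 array with an antiviral list median of 10.53, so turned signs here may come from exchanged codes alone. Both contested arrays are KO, so no WT change moved, and the WT calls were lost through the spread shared by all 4 groups. SLFN5 was 0.70 in WT (adjusted p = 0.262) and -0.001 in KO, and 5 lists were called in KO and 7 in the difference in response. Antiviral effectors turned with IFNβ (adjusted p = 0.000842), as did cytokines (0.539), and in the difference in response antiviral effectors (2.86e-22), sensing genes (0.000793) and cytokines (0.00181). Untreated, AIM2 turned to 0.257, MYD88 to 0.072 and MLKL to 0.332. With IFNβ, MX1 turned to -0.055, HERC6 to -0.595, DHX58 to -0.126, ZBP1 to -0.265, GBP2 to -0.08, TNFSF10 to -0.386 and TNFSF13B to -0.82.

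With the deposited values grouped by title, 0 genes were called for IFNβ in WT or KO or between KO and WT untreated or with IFNβ (limma, with 470, 472, 621 and 443 at unadjusted p under 0.05), and 0 were shared. By the codes each title group mixes both lines and both treatments. Lost calls and turned signs here may therefore come from the grouping alone. Grouped by code, the deposited values kept 225 of the 247 named calls. SLFN5 was -0.117 for IFNβ in WT, -0.102 between KO and WT with IFNβ and 0.283 for the difference in response. The tests called 7 lists between untreated KO and WT and 5 for the difference in response. These lists turned: hypoxia in WT (adjusted p = 0.007), DNA replication untreated (0.0108), antiviral effectors and cytokines with IFNβ (both 0.953), and in the difference in response antiviral effectors and sensing genes (both 0.929) and cytokines (0.989). For IFNβ in WT, TIGAR turned to 0.013, THBS2 to 0.113 and ID3 to -0.069. Untreated, STC2 turned to -0.052, SRGN to -0.104, UGDH to -0.371, ACKR3 to -0.08, MLKL to 0.064, TP53INP1 to -0.149 and ALDH1L1 to -0.223. With IFNβ, MSX1 turned to -0.103, HERC6 to -0.045, GBP5 to -0.071, TNFSF13B to -0.357, SOD2 to 0.096 and RPS23 to -0.081.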

Other observations

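Outside the interferon lists, SOX9, a neural and glial transcription factor, rose with IFNβ by 0.82 ± 0.15 on the log2 scale in WT and by 1.00 ± 0.18 in KO cells, among 4 and 3 of 18 glioma and neural progenitor genes that rose (4 up and 1 down in each line adjusted over the list alone, and as many with the replicate block). ITGA2, an integrin subunit, rose by 1.13 ± 0.13 and 0.85 ± 0.16, the only called member of 28 adhesion genes in each line. In the KO groups fitted alone, neither SOX9 nor ITGA2 was called (adjusted p = 0.0686 and 0.0513), and ITGA2 lost its call in KO without KO IFNβ replicate 1 (0.06) or KO untreated replicate 2 (0.0777). SLFN12, another Schlafen gene, rose by 0.54 ± 0.12 in WT and 0.67 ± 0.15 in KO cells. Its call was lost in KO without KO untreated replicate 1 (0.134) or KO IFNβ replicate 1 (0.147), and in WT without any of WT untreated replicates 1 and 2 and WT IFNβ replicates 2 and 3 (at most 0.0766).

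CDH11, a cadherin, was lower in KO than in WT by differences of -1.19 ± 0.12 untreated and -0.75 ± 0.12 with IFNβ, the only called member of 28 adhesion genes (1 up and 1 down untreated and 1 up and 2 down with IFNβ with the block). LUM, the matrix proteoglycan lumican, and THBS2, a thrombospondin, differed by -0.84 ± 0.17 and -0.61 ± 0.12 untreated, the 2 called of 28 extracellular matrix genes (5 up and 5 down with the block). Without KO untreated replicate 1, LUM and THBS2 were not called (adjusted p = 0.105 and 0.144), and LUM was also lost without KO untreated replicate 2 (0.115) or WT untreated replicates 1 or 3 (0.0813 and 0.0796).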
